A study of Mus musculus with 9 samples.

How the data were processed

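Lacrimal gland RNA of C57BL/6J female mice was measured in 9 libraries, 3 at each of 2, 12 and 24 months, and the titles of the youngest group read 8W. Per the labels' protocols, total RNA was extracted with the RNeasy Plus Micro kit and sequenced in pairs of 100 bp on a BGISEQ500RS. The labels do not say whether each library came from a separate mouse or a pool.

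The deposited counts are whole numbers of reads per gene; per the submitters' processing notes, cutadapt, FastQC, STAR, HTSeq and DESeq2 were used with the GRCm38 assembly, with no versions. The annotation release, the strand setting and the filters of reads are not given in the sources used here. The deposited log2 values were checked against the counts and equal log2(count / factor + 1) with a DESeq2 median-of-ratios factor for each library, with 100% of values within 1e-06. The counts were used for every test and the log2 values for this check only. Of 54232 genes 54165 had a symbol, and the 67 others held at most 0.001% of the counts of a library. Coordinates and gene types were taken from GENCODE M21.

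Genes were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling, filterByExpr with a minimum count of 10), with all 9 libraries in 1 model of the 3 ages. The comparisons were 12 against 2, 24 against 2 and 24 against 12 months, and the 3 ages together. The filter kept 14944 genes and at least 99.93% of the counts of each library. The common coefficient of variation was 21.2%, with 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all tested genes of a comparison and called under 0.05. The depth of 40516863 to 42573877 counts per library leaves genes of a few counts per library untested or known only within wide counting intervals. Where an age had 0 counts of a gene, the fold is given as a lower bound against a floor of 3 counts over the group. With 1 to 3 counts it is given as a ratio with a 95% counting interval.

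Gene sets were 36 lists of cell types and processes, with 541 distinct genes of which 7 were in more than 1 list, fixed before the data were examined. Each was tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the 36 lists of a comparison, where at least 3 genes were tested. Genes were also adjusted over the members of a list alone. Named genes followed a rule. The first part took the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 2 CPM over the 6 libraries and no overlap between ages, leaving out antigen receptor segments and predicted genes. The second part took up to 4 called members with the smallest p of each list, and the third 21 fixed genes in every comparison. From those the text names the ones that bear on each group. Some items of the third part are not reported here.

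Immunoglobulin measures (share of counts, heavy chain class shares, V segment diversity) were tested for a slope on months with a two-sided exact permutation test over 1680 arrangements. For the effective number of V segments, counts were thinned 200 times to equal counts, while the share of the most abundant segment used all counts. Values were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 and drawn with matplotlib 3.10.9.

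The alternatives planned were RLE scaling, other count filters, DESeq2 1.42.0, limma voom with sample weights, no antigen receptor genes, the replicate number as a block, only the libraries compared, each library left out in turn, stricter thresholds, camera with an estimated correlation, and the fry test, and for the immunoglobulin measures age rank in place of months, a total without the 10 most abundant genes, and no thinning. The following were added after the data were seen: leaving out the 3 libraries with the most salivary gland transcripts (2-month replicate 3, 12-month replicate 2, 24-month replicate 2), those transcripts as a covariate, leaving out the 2 libraries with skeletal muscle transcripts (12-month replicates 1 and 3), and scaling by library totals alone. Tests of gene families were also chosen after the data were seen.

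The procedure was tested on simulated data with 200 changed genes in each comparison. Of changes of 1 log2 unit it recovered 53, 47 and 59% for 12 against 2, 24 against 2 and 24 against 12 months, and of changes of 2 units 83, 82 and 80%. False calls were 8 of 144, 4 of 133 and 11 of 150. With those 200 genes drawn without regard to the lists, 0 of 36 lists were called in each comparison. With 1 list moved, that list and 2 others were called. With no change simulated, 0 genes were called across the 3 ages, and lists were not tested there. Each gene was simulated on its own, so the simulation does not cover correlation between the genes of a list.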

Results

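RNA was measured in lacrimal glands, the glands that secrete the watery part of the tear film, of C57BL/6J female mice at 3 ages. There were 3 libraries at each of 2, 12 and 24 months, 9 in all, and the title of the series places the study in the formation of lymphoid tissue inside the old gland. Each library held between 40516863 and 42573877 counts over 54232 genes, and 14944 genes had enough counts to be tested. The 10 most abundant genes took 61.1 to 67.8% of the counts of a library, led by the odorant binding protein gene Obp1a with 15.62 to 18.79%. Genes with at least 1 count numbered 19584 ± 630 (SD, n = 3 libraries) at 2 months, 23122 ± 520 at 12 months and 21787 ± 702 at 24 months. On the first principal component, which held 45.3% of the variance, the 2-month libraries lay between -77.6 and -55.5 and the others between 1.5 and 50.2. On the second, with 16% of the variance, the 12-month libraries lay between -38.6 and -29.6 and the 24-month libraries between 31 and 34. Levels are given in CPM, scaled by TMM, as mean ± SD over the 3 libraries of an age. The labels do not say that the libraries of an age came from separate mice, so the p-values measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only.

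The genes followed through the text lie at these places in the GRCm38 assembly. Among immune genes they are Ms4a1 (ENSMUSG00000024673, chromosome 19, 11249675 to 11266241), Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068) and Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730). Ctss (ENSMUSG00000038642) lies on chromosome 3, 95526786 to 95556403. Among gland genes they are Scgb2b7 (ENSMUSG00000094053, chromosome 7, 31703779 to 31705757), Scgb2a2 (ENSMUSG00000096872, chromosome 19, 9847562 to 9852808) and Pnliprp1 (ENSMUSG00000042179, chromosome 19, 58728887 to 58744169). Dio1 (ENSMUSG00000034785) lies on chromosome 4, 107291465 to 107307169, and Slco1a6 (ENSMUSG00000079262) on chromosome 6, 142085761 to 142208521.

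Transcripts typical of salivary gland, skeletal muscle and fat were present in some libraries, and the tissue they came from was not tested. Bpifa2, a protein secreted by salivary glands, had 8, 1829 and 22857 counts in replicates 1, 2 and 3 at 2 months, 178, 14351 and 32 at 12 months, and 201, 8709 and 8 at 24 months. Amy1, salivary amylase, was highest in the same 3 libraries, with 3194 counts in 2-month replicate 3, 2952 in 12-month replicate 2 and 1825 in 24-month replicate 2. Acta1, the actin of skeletal muscle, had 341 and 985 counts in replicates 1 and 3 at 12 months and at most 17 in any other library. Adipoq, the adipocyte hormone adiponectin, had 1, 1 and 1 counts at 2 months, 4, 97 and 90 at 12 months, and 50, 130 and 15 at 24 months. Of the 6 tested genes in the list of salivary gland products none passed the test in any comparison, nor adjusted over the list alone, and the list was not called (camera adjusted p = 0.301 for 12 against 2 months, 0.597 for 24 against 2 and 0.79 for 24 against 12).

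**Figure D1:**
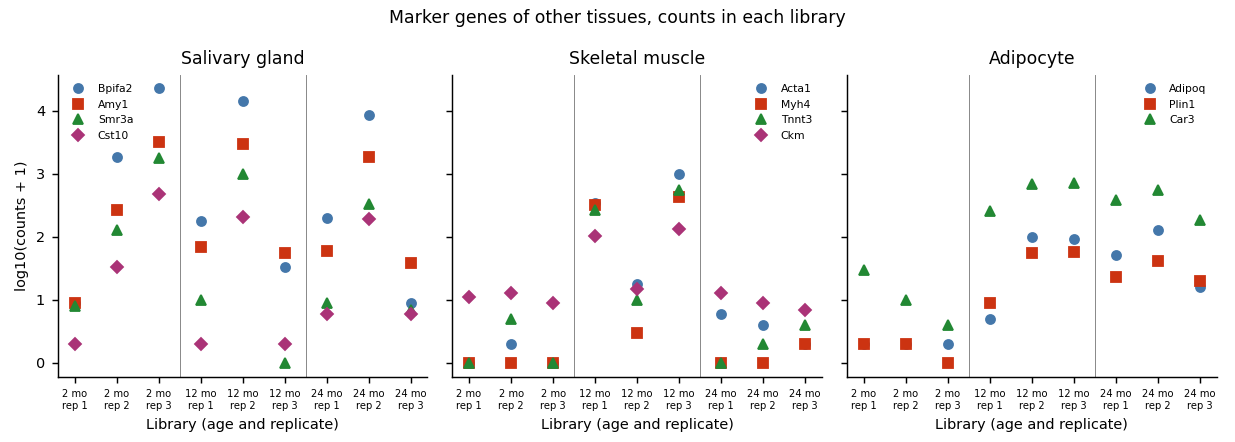
Counts of 4 salivary gland, 4 skeletal muscle and 3 adipocyte transcripts in each of the 9 libraries, drawn as log10(counts + 1) with 1 point per library and gene. Bpifa2 reached 22857, 14351 and 8709 counts in 1 library of each age, and Acta1 reached 341 and 985 counts in 2 libraries of 12 months.

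The comparison of 12 with 2 months asks what differs in the gland of a middle-aged mouse. The lists of B cells, T cells, immunoglobulins, macrophages, MHC class II and adipocytes were called higher at 12 months (adjusted p between 0.131 and 0.189 with an estimated correlation), with many genes up from near 0. Several secretoglobins, Fgg and Pnliprp1 were lower, while the list of acinar and tear secretion genes was not called (camera adjusted p = 0.722). All 20 tested B cell genes rose. The secreted proteins Scgb2b7, Scgb1b7 and Fgg fell more than 10-fold, while the lacrimal products Ltf and the water channel Aqp5 did not pass the test. Of 14944 genes, 808 rose and 377 fell at an adjusted p under 0.05 (edgeR quasi-likelihood test), of which 666 and 99 differed at least 2-fold. Of the 118 tested immunoglobulin and T cell receptor genes, 63 rose and 0 fell. The 2-month libraries held 11, 8 and 168 Ighv counts and 53, 32 and 491 Igkv counts in all. V segments thus passed the count filter mainly through the older ages, and few could have fallen. Scaling by library totals alone gave 1614 higher and 80 lower genes, because it moved the median log2 fold change of all genes to 0.31, against 0.01 with TMM (in 24 against 2 months also 0.31, against 0.01).

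Ms4a1, which encodes the B cell antigen CD20, rose from 0.0358 ± 0.0121 to 11.2 ± 8.37 CPM (log2 fold change 8.15, SE 0.90, adjusted p = 0.00059). Cd79a, a signalling chain of the B cell receptor, rose from 0.0927 ± 0.0477 to 25.1 ± 19.8 CPM (8.06, SE 0.92, adjusted p = 0.00059). Ighm, the heavy chain of IgM, rose from 3.19 ± 1.61 to 512 ± 303 CPM (7.32, SE 0.61, adjusted p = 0.000192). Ighg2b rose from 0.159 ± 0.255 to 106 ± 74.6 CPM (9.39, adjusted p = 0.00077). Ighd, the heavy chain of naive B cells, rose from 0.246 ± 0.215 to 31.8 ± 24.4 CPM (6.99, adjusted p = 0.00265). Reads of the near-identical Ighg genes can be assigned to one another, so their single values are uncertain. Of the 20 B cell genes, 20 rose, also 20 adjusted over the list alone, with a median log2 fold change of 6.83 (camera adjusted p = 7.76e-45). Of 11 immunoglobulin constant regions 9 rose, 9 adjusted over the list alone (median 6.99, adjusted p = 6.69e-15). Of 13 plasma cell markers 7 rose and 0 fell, 9 and 1 adjusted over the list alone (median 2.56, adjusted p = 6.14e-06). Each of these 3 lists had an adjusted p = 0.131 with an estimated correlation. Jchain, which joins the subunits of secreted IgM and IgA, rose from 6.63 ± 10.1 to 72.4 ± 45.5 CPM (3.46, SE 0.91, adjusted p = 0.0373). Jchain lost this call without 12-month replicate 1 (adjusted p = 0.0825) or 2 (0.139), 2-month replicate 1 (0.084) or 2 (0.116). Its counts at 2 months were 38, 23 and 646, so replicate 3 carries most of that mean. Igha, the heavy chain of IgA, was at 27.1 ± 39.6 and 73.2 ± 33.8 CPM and did not pass the test (adjusted p = 0.468); its counts at 2 months were 186, 132 and 2576, the last in the library with the most Bpifa2.

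Of 9 tested genes in the list of germinal centre B cells 2 rose, 7 adjusted over the list alone (median 1.02, adjusted p = 0.000345; adjusted p = 0.193 with an estimated correlation). They were Fcrl5, an Fc receptor-like protein of B cells, and Bcl6, a transcription repressor of germinal centre B cells that is also made outside the immune system. Fcrl5 had 0 counts at 2 months and was at least 20.2-fold higher against a floor of 3 counts over the group (adjusted p = 0.0199). Fcrl5 lost this call without 12-month replicate 2 (adjusted p = 0.0705), 2-month replicate 2 (0.0705) or 3 (0.0598). Bcl6 rose from 19.3 ± 4.49 to 37.4 ± 12.8 CPM (log2 fold change 0.95, adjusted p = 0.0354). Bcl6 lost this call without 12-month replicate 1 (adjusted p = 0.103) or 3 (0.102), the 2 libraries with skeletal muscle transcripts, or 2-month replicate 2 (0.157) or 3 (0.116). The follicular helper cytokine gene Il21 had 0 counts at 2 months, 3, 4 and 4 at 12 months and 0, 0 and 1 at 24 months. Icos had 0, 1 and 0, then 6, 14 and 0, then 1, 0 and 1. Ifng, interferon gamma, had 1, 0 and 0, then 5, 0 and 1, then 1, 0 and 1. Of 12 tested follicular helper T cell genes 5 rose, 9 adjusted over the list alone (median 2.09, or 1.97 with genes of 0 counts at their bound, adjusted p = 9.27e-08; adjusted p = 0.131 with an estimated correlation).

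Most T cell genes and several signals of lymphoid tissue rose. Cd4 rose from 0.222 ± 0.121 to 4.84 ± 2.67 CPM (log2 fold change 4.40, SE 0.58, adjusted p = 0.00112). Cd8a rose from 0.0679 ± 0.0934 to 1.46 ± 0.795 CPM (4.30, SE 0.77, adjusted p = 0.00617). Cd3e, a chain of the T cell receptor complex, rose from 0.159 ± 0.0735 to 1.99 ± 1.19 CPM (3.64, SE 0.64, adjusted p = 0.00543). Cxcl13, the chemokine that draws B cells into follicles, had 2 counts over the 2-month group and 695 at 12 months, a ratio of 277 with a 95% counting interval of 76.5 to 2300 (adjusted p = 0.00077), and its receptor Cxcr5 had 1 and 612 counts, a ratio of 489 with an interval of 87.4 to 19300 (adjusted p = 0.00079). Ltb, lymphotoxin beta, rose from 0.489 ± 0.0733 to 8.59 ± 5.3 CPM (4.12, SE 0.54, adjusted p = 0.0012). Cxcr4, the receptor of Cxcl12, rose from 0.371 ± 0.0504 to 3.98 ± 1.5 CPM (3.41, SE 0.33, adjusted p = 0.000461). Glycam1, a mucin of high endothelial venules, rose from 0.0732 ± 0.0873 to 10.6 ± 7.72 CPM (7.12, SE 1.08, adjusted p = 0.00266). Ccl19, a chemokine of the T cell zone, was not tested, with 2 counts over the 2-month group, 14 at 12 months and 12 at 24 months. Of 19 T cell genes 16 rose, 18 adjusted over the list alone (median 3.58, adjusted p = 2.74e-23). Of 17 lymphoid tissue chemokine and lymphotoxin genes 11 rose, 12 adjusted over the list alone (median 2.22, adjusted p = 2.07e-13). Both lists had an adjusted p = 0.131 with an estimated correlation. Of 11 cytotoxic lymphocyte genes 6 rose, 9 adjusted over the list alone (median 2.16, adjusted p = 1.83e-09; adjusted p = 0.139 with an estimated correlation). Of 8 high endothelial venule genes 2 rose, 5 adjusted over the list alone (median 1.28, adjusted p = 0.00118; adjusted p = 0.245 with an estimated correlation).

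All MHC class II genes, and some of the macrophage, complement and MHC class I genes, rose as well. Ctss, the lysosomal protease cathepsin S, rose from 17.1 ± 3.24 to 59.6 ± 5.95 CPM (log2 fold change 1.80, SE 0.16, adjusted p = 0.000228). Lyz2, a lysozyme of macrophages, rose from 20.7 ± 8.83 to 106 ± 20.5 CPM (2.35, SE 0.28, adjusted p = 0.000691). Cd68 rose from 3.92 ± 0.852 to 15.4 ± 3.1 CPM (1.97, SE 0.19, adjusted p = 0.000461). C3, the central complement component, rose from 5.34 ± 2.18 to 31.8 ± 10.8 CPM (2.57, SE 0.33, adjusted p = 0.00106). Mmp12, the macrophage elastase, rose from 0.76 ± 0.23 to 5.94 ± 2.29 CPM (2.96, adjusted p = 0.00108). Of 18 macrophage and monocyte genes 8 rose and 1 fell, 9 and 2 adjusted over the list alone (median 0.81, adjusted p = 6.01e-09). Of 13 dendritic cell genes 3 rose, 5 adjusted over the list alone (median 1.19, adjusted p = 3.05e-05). Both lists had an adjusted p = 0.189 with an estimated correlation. All 11 MHC class II genes rose, 11 adjusted over the list alone (median 1.58, adjusted p = 3.72e-16; adjusted p = 0.131 with an estimated correlation), with H2-Ob, a class II modulator of B cells, up from 0.261 ± 0.158 to 10.2 ± 7.91 CPM (5.26, adjusted p = 0.00323). Of 15 MHC class I genes 8 rose, 9 adjusted over the list alone (median 0.93, adjusted p = 2.67e-07; adjusted p = 0.258 with an estimated correlation). Of 10 complement genes 4 rose, 7 adjusted over the list alone (median 0.85, adjusted p = 5.77e-08; adjusted p = 0.139 with an estimated correlation). Of 17 genes induced by interferon gamma 2 rose, 5 adjusted over the list alone (median 0.62, adjusted p = 0.00131; adjusted p = 0.482 with an estimated correlation). The 3 of 14 genes of the senescence list that rose, 3 adjusted over the list alone, were Mmp12, the chemokine gene Ccl8 and Spp1, osteopontin, all made by macrophages (median 0.29, adjusted p = 0.00265; adjusted p = 0.131 with an estimated correlation; 0.062 without 12-month replicate 3). Of 10 cathepsins Ctss alone rose over all genes, 3 adjusted over the list alone (median 0.06, adjusted p = 0.0271; adjusted p = 0.254 with an estimated correlation). This list call was lost without 2-month replicate 3 (0.0667) or 12-month replicate 3 (0.0777). The call of Ccl8 was lost without 12-month replicate 2 (0.0713) or 2-month replicate 2 (0.0925).

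Among the secreted products of the gland, Scgb2b7 fell from 2960 ± 1260 to 143 ± 80.3 CPM (log2 fold change -4.38, SE 0.56, adjusted p = 0.00103). Scgb1b7 fell from 604 ± 280 to 31 ± 14.3 CPM (-4.29, SE 0.51, adjusted p = 0.000755). Scgb2a2 fell from 314 ± 53.4 to 30.9 ± 11.5 CPM (-3.35, SE 0.34, adjusted p = 0.000461). These are secretoglobins, small secreted proteins, and reads of near-identical members can be assigned to one another, so single values are uncertain. Fgg, a chain of fibrinogen, fell from 289 ± 39.8 to 20.7 ± 12.2 CPM (-3.80, SE 0.41, adjusted p = 0.000582). Camk2b, a calcium-regulated kinase subunit, fell from 6.08 ± 2.08 to 0.323 ± 0.145 CPM (-4.21, SE 0.54, adjusted p = 0.00106). The lipase-related Pnliprp1 fell from 2940 ± 844 to 348 ± 109 CPM (-3.08, SE 0.69, adjusted p = 0.0181). Pnliprp1 lost this call without 12-month replicate 1 (adjusted p = 0.0654) or 2 (0.0939), or 2-month replicate 2 (0.0736). Ltf, lactoferrin, was at 1320 ± 61.9 and 1360 ± 75.2 CPM (adjusted p = 0.92), Aqp5 at 279 ± 24.4 and 271 ± 21.4 CPM (adjusted p = 0.864), and Pigr, which carries IgA and IgM across the epithelium, at 697 ± 68.3 and 993 ± 131 CPM (adjusted p = 0.0768). Of 22 acinar and tear secretion genes 1 rose and 1 fell, 4 and 2 adjusted over the list alone (median 0.04, adjusted p = 0.722).

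Of the contractile myoepithelial and smooth muscle genes Acta2 fell from 83 ± 8.41 to 49.7 ± 2.65 CPM (log2 fold change -0.74, SE 0.11, adjusted p = 0.0021). Myh11 fell from 31.8 ± 5.64 to 18.8 ± 1.75 CPM (-0.76, SE 0.14, adjusted p = 0.00841), while Des, desmin, which skeletal muscle also makes, rose from 0.99 ± 0.25 to 3.65 ± 0.753 CPM (1.89, SE 0.27, adjusted p = 0.0021). Of these 10 genes 3 fell and 1 rose, 5 and 1 adjusted over the list alone (median -0.47, adjusted p = 0.00189; adjusted p = 0.139 with an estimated correlation). All 4 tested skeletal muscle genes rose, 4 adjusted over the list alone (median 2.92, adjusted p = 0.000574; adjusted p = 0.214 with an estimated correlation), and the list call was lost without the 2 libraries of 12 months that hold Acta1 (adjusted p = 0.638). Of 12 adipocyte genes 9 rose, 10 adjusted over the list alone (median 4.71, or 4.14 with genes of 0 counts at their bound, adjusted p = 1.85e-11; adjusted p = 0.133 with an estimated correlation), with Car3, a carbonic anhydrase, up from 0.357 ± 0.329 to 12 ± 5.39 CPM (5.01, adjusted p = 0.000987), beside 4, 97 and 90 counts of Adipoq. Of 18 cell division genes 0 rose and 2 fell, 10 adjusted over the list alone (median -1.09, adjusted p = 7.63e-07; adjusted p = 0.258 with an estimated correlation). None of them fell with library totals alone (median -0.80). The lists of oxidative phosphorylation, the unfolded protein response and fibroblasts were called lower with small medians of -0.20, -0.20 and -0.15, which turned to 0.10, 0.10 and 0.13 with library totals alone. Of their 19, 17 and 17 genes 4, 0 and 1 fell, 7, 0 and 1 adjusted over the list alone (adjusted p = 0.000158, 0.00651 and 0.04999; adjusted p = 0.245, 0.482 and 0.579 with an estimated correlation). With library totals alone 0, 0 and 0 fell, and the calls of the oxidative phosphorylation and unfolded protein response lists were lost (adjusted p = 0.111 for each). The call of the unfolded protein response list was lost without 12-month replicate 3 (0.0848), and that of the fibroblast list without 2-month replicate 1 (0.0934) or 3 (0.545) or 12-month replicate 1 (0.0959) or 3 (0.0992). The fibroblast call, barely under 0.05, was also lost with RLE scaling (0.0505), with salivary gland transcripts as a covariate (0.0516), without antigen receptor genes (0.0518) and with a mean of at least 1 CPM (0.0647).

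The count of 1185 genes for 12 against 2 months fell to 435 without 2-month replicate 2, 594 without 2-month replicate 3, 445 without 12-month replicate 2, 696 without 12-month replicate 1, 127 without the 3 libraries with the most salivary gland transcripts and 746 without the 2 with skeletal muscle transcripts. Of the 99 calls of single genes in this comparison that the naming rule covers, 61 were lost without the 3 salivary libraries and 41 with limma voom and sample weights, Ms4a1, Cd79a, Cxcl13, Cxcr5, Glycam1, Ighg2b, Ighd, H2-Ob and Car3 among the latter (adjusted p between 0.0609 for Car3 and 0.221 for Glycam1). Among those lost without the salivary libraries were Ighd, Glycam1, Cd3e, Cd8a, H2-Ob, Acta2, Myh11, Des and Pnliprp1 (adjusted p between 0.0549 for Des and 0.222 for Pnliprp1). When salivary gland transcripts were a covariate in all 9 libraries, 8 of the 99 calls were lost. Leaving out 3 libraries also leaves fewer per age, so the 61 losses cannot be ascribed to salivary tissue alone. The list calls of cathepsins, fibroblasts and the unfolded protein response were also lost without the salivary libraries (adjusted p between 0.0877 for the unfolded protein response and 0.379 for fibroblasts). Those of cathepsins, fibroblasts and senescence were lost without the muscle libraries (adjusted p between 0.0772 for cathepsins and 0.27 for fibroblasts). The fry test called 17 of the 24 lists. It did not call high endothelial venules (adjusted p = 0.0519), skeletal muscle (0.0712), MHC class I presentation (0.0823), cell division (0.0892), interferon gamma induced genes (0.141), the unfolded protein response (0.141) or fibroblasts (0.42).

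**Figure D2:**
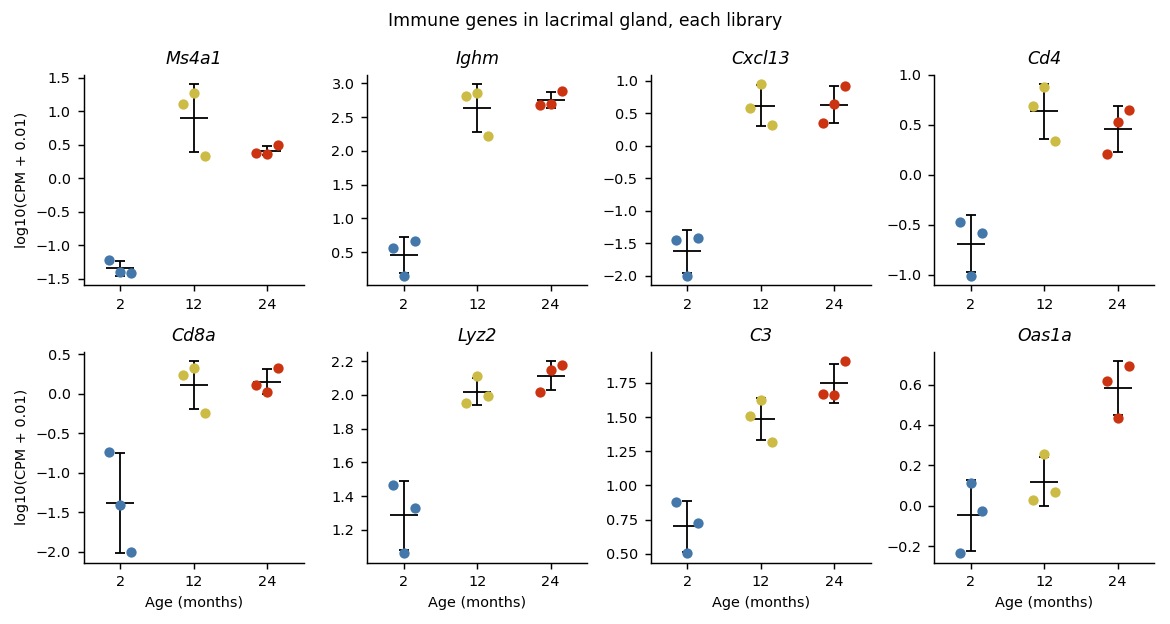
Levels of 8 genes of immune cells, as log10(CPM + 0.01), in the 3 libraries of each age, with 1 point per library and a black line for the mean and SD of the log values. Ighm rose from a mean of 3.19 CPM at 2 months to 512 CPM at 12 and 577 CPM at 24 months, while Ms4a1 was at 0.0358, 11.2 and 2.59 CPM.

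The comparison of 24 with 2 months asks what differs in the gland of an old mouse. The lists of immunoglobulins, macrophages, mast cells, complement and interferon-induced genes were called higher (adjusted p between 0.132 and 0.381 with an estimated correlation), though only 9 of 17 genes induced by interferon gamma and 6 of 22 by type I interferon rose. Dio1, the deiodinase that converts thyroxine to active thyroid hormone, rose from near 0 to over 100 CPM. Secreted and transport proteins of the gland, Pnliprp1, Scgb2a2 and the organic anion transporter Slco1a6, fell more than 10-fold. Of 14944 genes, 1467 rose and 1130 fell (edgeR, adjusted p under 0.05), of which 993 and 158 differed at least 2-fold, and of 118 immunoglobulin and T cell receptor genes 87 rose and 0 fell. Here too, V segments passed the count filter mainly through the older ages, so few could have fallen. With library totals alone the split was 2626 higher and 191 lower.

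Ighm rose from 3.19 ± 1.61 to 577 ± 166 CPM (log2 fold change 7.49, SE 0.61, adjusted p = 4.36e-05). Ighg2b rose from 0.159 ± 0.255 to 105 ± 72.2 CPM (9.37, SE 1.13, adjusted p = 0.000414). Ms4a1 rose from 0.0358 ± 0.0121 to 2.59 ± 0.434 CPM (6.04, SE 0.97, adjusted p = 0.00234). Prdm1, a transcription factor of plasma cells, rose from 0.475 ± 0.24 to 1.76 ± 0.113 CPM (1.88, SE 0.37, adjusted p = 0.00618). Jchain rose from 6.63 ± 10.1 to 99.1 ± 26 CPM (3.91, SE 0.93, adjusted p = 0.0146). Jchain lost this call without 2-month replicate 2 (adjusted p = 0.0516). Igha was at 27.1 ± 39.6 and 138 ± 163 CPM (adjusted p = 0.164), with 587, 14092 and 3755 counts at 24 months, the highest in the library with the most Bpifa2 of that age. Of 20 B cell genes 16 rose, 18 adjusted over the list alone (median 4.34, adjusted p = 9.51e-19). Of 11 immunoglobulin constant regions 8 rose, 9 adjusted over the list alone (median 6.56, adjusted p = 1.08e-09). Both lists had an adjusted p = 0.172 with an estimated correlation. Of 13 plasma cell markers 9 rose and 1 fell, 9 and 1 adjusted over the list alone (median 2.19, adjusted p = 4.71e-06; adjusted p = 0.132 with an estimated correlation). Of 9 germinal centre genes 4 rose, 4 adjusted over the list alone (median 1.15, adjusted p = 0.00746; adjusted p = 0.335 with an estimated correlation). They were Fcrl5, Basp1, S1pr2 and Elk3, of which Basp1, a membrane-bound signalling protein, and Elk3, a transcription factor of endothelium, are widely made outside B cells. S1pr2 lost its call without 2-month replicate 2 (0.0737) or 3 (0.0881) or 24-month replicate 2 (0.0617) or 3 (0.0993), and Elk3 without 2-month replicate 1 (0.064) or 2 (0.118) or 24-month replicate 2 (0.0911) or 3 (0.108). Bcl6 was at 19.3 ± 4.49 and 24.7 ± 5.86 CPM (adjusted p = 0.355).

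Cd4 rose from 0.222 ± 0.121 to 3.14 ± 1.44 CPM (log2 fold change 3.78, SE 0.57, adjusted p = 0.00174). Cd8a rose from 0.0679 ± 0.0934 to 1.48 ± 0.558 CPM (4.32, SE 0.77, adjusted p = 0.0039). Cd3e rose from 0.159 ± 0.0735 to 1.27 ± 0.572 CPM (3.0, SE 0.64, adjusted p = 0.00875). Cxcl13 had 2 and 686 counts, a ratio of 286 with a 95% counting interval of 78.8 to 2360 (adjusted p = 0.000414), and Cxcr5 had 1 and 144 counts, a ratio of 120 with an interval of 21.2 to 4770 (adjusted p = 0.00339). Ltb rose from 0.489 ± 0.0733 to 2.91 ± 1.34 CPM (2.57, SE 0.54, adjusted p = 0.0086). Vcam1 rose from 1.46 ± 0.386 to 6.26 ± 1.81 CPM (2.11, SE 0.29, adjusted p = 0.000858). Of 19 T cell genes 13 rose, 16 adjusted over the list alone (median 2.75, adjusted p = 2.44e-11). Of 12 follicular helper T cell genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone (median 1.95, or 1.84 with genes of 0 counts at their bound, adjusted p = 0.00037). Both lists had an adjusted p = 0.262 with an estimated correlation. Of 11 cytotoxic lymphocyte genes 7 rose, 10 adjusted over the list alone (median 2.56, adjusted p = 1.69e-07; adjusted p = 0.216 with an estimated correlation). Of 17 lymphoid tissue chemokine and lymphotoxin genes 11 rose, 13 adjusted over the list alone (median 2.11, adjusted p = 1.38e-10; adjusted p = 0.163 with an estimated correlation). Of 8 high endothelial venule genes 4 rose, 4 adjusted over the list alone (median 1.10, adjusted p = 0.00104; adjusted p = 0.271 with an estimated correlation). The list of regulatory T cells was not called in any comparison (adjusted p = 0.132 for 12 against 2 months, 0.125 for 24 against 2 and 0.846 for 24 against 12).

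Lyz2 rose from 20.7 ± 8.83 to 132 ± 24.3 CPM (log2 fold change 2.67, SE 0.28, adjusted p = 0.000166). Cd68 rose from 3.92 ± 0.852 to 19.6 ± 2.68 CPM (2.32, SE 0.19, adjusted p = 4.58e-05). Ctss rose from 17.1 ± 3.24 to 61.1 ± 11.5 CPM (1.83, SE 0.16, adjusted p = 6.58e-05). Mcpt4, a protease of mast cells, rose from 0.128 ± 0.115 to 2.92 ± 1.11 CPM (4.48, SE 0.57, adjusted p = 0.000625). C3 rose from 5.34 ± 2.18 to 57.8 ± 20 CPM (3.43, SE 0.34, adjusted p = 0.000131). C4b rose from 1.12 ± 0.643 to 10.5 ± 2.38 CPM (3.22, SE 0.40, adjusted p = 0.000497). B2m, the invariant chain of MHC class I, rose from 61.4 ± 7.48 to 191 ± 83.2 CPM (1.64, adjusted p = 0.00319). Oas1a, an antiviral enzyme induced by interferon, rose from 0.933 ± 0.359 to 3.92 ± 1.13 CPM (2.08, adjusted p = 0.00305). Of 18 macrophage and monocyte genes 13 rose, 14 adjusted over the list alone (median 1.42, adjusted p = 9.51e-19). All 6 granulocyte and mast cell genes rose, 6 adjusted over the list alone (median 2.82, adjusted p = 4.71e-06). Of 10 complement genes 8 rose, 10 adjusted over the list alone (median 1.66, adjusted p = 1.9e-14). Of 10 cathepsins 4 rose, 6 adjusted over the list alone (median 0.51, adjusted p = 3.05e-05). Each of these 4 lists, and the senescence list, of whose 14 genes 5 rose, 5 adjusted over the list alone (median 0.80, adjusted p = 0.000356), had an adjusted p = 0.132 with an estimated correlation. Of 13 dendritic cell genes 5 rose, 6 adjusted over the list alone (median 1.26, adjusted p = 0.000478). Of 15 MHC class I genes 11 rose, 14 adjusted over the list alone (median 1.02, adjusted p = 5.25e-08). Both lists had an adjusted p = 0.271 with an estimated correlation. Of 11 MHC class II genes 10 rose, 11 adjusted over the list alone (median 1.10, adjusted p = 5.25e-08; adjusted p = 0.262 with an estimated correlation). Of 17 genes induced by interferon gamma 9 rose, 14 adjusted over the list alone (median 1.40, adjusted p = 9.58e-07; adjusted p = 0.282 with an estimated correlation). Of 22 induced by type I interferon 6 rose, 10 adjusted over the list alone (median 1.01, adjusted p = 1.57e-05; adjusted p = 0.381 with an estimated correlation). The cell cycle inhibitor gene Cdkn2a, a marker of senescence, was not tested and had 1 count over the 2-month group and 4, 28 and 64 counts at 24 months, a ratio of 80 with a 95% counting interval of 14 to 3190.

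Dio1 rose from 0.208 ± 0.0375 to 122 ± 23.4 CPM (log2 fold change 9.16, SE 0.24, adjusted p = 7.01e-10). Pnliprp1 fell from 2940 ± 844 to 144 ± 114 CPM (-4.35, SE 0.73, adjusted p = 0.00284). Scgb2a2 fell from 314 ± 53.4 to 27.2 ± 11.5 CPM (-3.53, SE 0.34, adjusted p = 0.000118). Slco1a6 fell from 13.3 ± 1.6 to 1.23 ± 0.337 CPM (-3.44, SE 0.21, adjusted p = 6.65e-06). Esp31, an exocrine gland-secreted peptide, fell from 1860 ± 133 to 193 ± 154 CPM (-3.27, SE 0.64, adjusted p = 0.006). Bhlha15, a transcription factor of secretory cells, fell from 535 ± 12.7 to 387 ± 16.2 CPM (-0.47, SE 0.11, adjusted p = 0.0127), a call lost with library totals alone (adjusted p = 0.328). Ltf was at 1320 ± 61.9 and 1340 ± 355 CPM (adjusted p = 0.951), Aqp5 at 279 ± 24.4 and 264 ± 11.1 CPM (adjusted p = 0.668) and Pigr at 697 ± 68.3 and 906 ± 159 CPM (adjusted p = 0.131). Of 22 acinar and tear secretion genes 4 rose and 1 fell, 4 and 1 adjusted over the list alone, and the list was not called (median 0.05, adjusted p = 0.40 here and 0.552 for 24 against 12 months). Of these genes 6 rose and 0 fell with library totals alone.

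Pdgfra, a receptor of fibroblasts, rose from 3.14 ± 1.12 to 7.58 ± 2.08 CPM (log2 fold change 1.27, SE 0.26, adjusted p = 0.00787). Of 17 fibroblast and extracellular matrix genes 8 rose, 9 adjusted over the list alone (median 0.66, adjusted p = 0.000478; adjusted p = 0.388 with an estimated correlation). Of 12 adipocyte genes 9 rose, 9 adjusted over the list alone (median 3.67, or 2.76 with genes of 0 counts at their bound, adjusted p = 4.1e-07; adjusted p = 0.239 with an estimated correlation), beside 50, 130 and 15 counts of Adipoq. Of 5 erythrocyte genes 4 rose, 5 adjusted over the list alone (median 1.42, adjusted p = 0.00044; adjusted p = 0.271 with an estimated correlation), with the globin gene Hbb-bs up from 21.2 ± 2.56 to 61.4 ± 30.3 CPM (1.53, adjusted p = 0.00592). Of 19 oxidative phosphorylation genes 5 fell, 5 adjusted over the list alone (median -0.16, which turned to 0.14 with library totals alone, adjusted p = 0.0037; adjusted p = 0.374 with an estimated correlation). With library totals alone 1 of them rose and 0 fell, and the list call was lost (adjusted p = 0.287). The lists of ductal epithelium (camera adjusted p = 0.66 for 12 against 2 months, 0.779 for 24 against 2, 0.95 for 24 against 12), Schwann cells (0.322, 0.216 and 0.699), cholesterol synthesis (0.134, 0.602 and 0.481) and immediate early and heat shock genes (0.66, 0.114 and 0.138) were not called by camera in any comparison. For 24 against 2 months the fry test called Schwann cells (adjusted p = 0.0426) and immediate early and heat shock genes (0.0332) higher.

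The count of 2597 genes for 24 against 2 months fell to 1160 without 2-month replicate 2, 1476 without 2-month replicate 3, 1405 without 24-month replicate 3 and 626 without the 3 libraries with the most salivary gland transcripts. Of the 134 calls of single genes that the naming rule covers here, 53 were lost without those 3 libraries, among them Bhlha15 (adjusted p = 0.186) and Esp31 (0.067), and 40 with limma voom and sample weights, among them Ms4a1, Cxcl13, Cxcr5, Ighg2b, Cd3e and Ltb (adjusted p between 0.0537 for Cxcl13 and 0.271 for Ms4a1). With those weights 1170 genes rose and 1176 fell, so the majority of rises did not hold. The list calls of fibroblasts (adjusted p = 0.0622) and type I interferon induced genes (0.0649) were lost with the fry test. When salivary gland transcripts were a covariate in all 9 libraries, 5 of the 134 calls of single genes were lost.

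**Figure D3:**
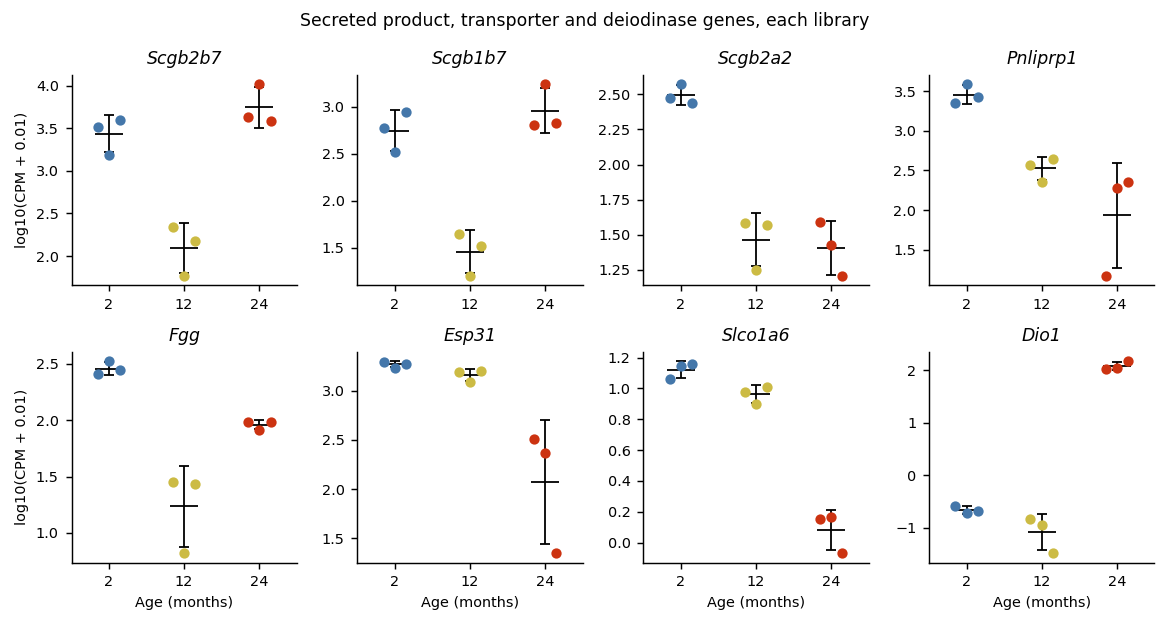
Levels of 8 secreted, transport and enzyme genes of the gland, as log10(CPM + 0.01), in the 3 libraries of each age, with 1 point per library and a black line for the mean and SD of the log values. Scgb2b7 stood at means of 2960, 143 and 6190 CPM at 2, 12 and 24 months, and Dio1 at 0.208, 0.0868 and 122 CPM.

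The comparison of 24 with 12 months asks what differs between the middle-aged and the old gland. The B cell list was called lower at 24 months, with 7 of 20 genes down, while immunoglobulin constant regions and plasma cell markers were not called. The lists of macrophages (3 of 18 genes up), mast cells (2 of 6), extracellular matrix (7 of 17), complement (2 of 10) and the response to type I interferon (7 of 22) were called higher. With library totals alone, 5 of the B cell genes fell, and 2 macrophage, 1 mast cell, 1 extracellular matrix, 0 complement and 2 type I interferon genes rose. These 6 calls were lost with an estimated correlation (adjusted p between 0.354 and 0.396) and with the fry test (between 0.0619 and 0.194). The secretoglobins Scgb2b7 and Scgb1b7, low at 12 months, rose, while Scgb2a2 stayed low. Dio1 rose, and the transporters Slco1a5 and Slco1a6 fell. Of 14944 genes 417 rose and 239 fell (edgeR, adjusted p under 0.05), of which 204 and 77 differed at least 2-fold, and of 118 immunoglobulin and T cell receptor genes 2 rose and 2 fell.

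Cr2, the complement receptor of mature B cells, fell from 3.91 ± 3.34 to 0.136 ± 0.0236 CPM (log2 fold change -4.82, SE 0.83, adjusted p = 0.00737). Fcer2a, the IgE receptor of naive B cells, fell from 8.63 ± 6.29 to 0.336 ± 0.332 CPM (-4.64, SE 0.85, adjusted p = 0.00972). Ighd fell from 31.8 ± 24.4 to 2.02 ± 1.73 CPM (-3.94, SE 0.79, adjusted p = 0.0161). Without 12-month replicate 1, 12-month replicate 2 or 24-month replicate 2 the adjusted p of Ighd was 0.055, 0.0623 and 0.0559. In 12-month replicate 3, Ighd had 215 counts, against 1685 and 2564 in the other libraries of that age. Of 20 B cell genes 7 fell, 16 adjusted over the list alone (median -2.07, adjusted p = 1.75e-10; adjusted p = 0.396 with an estimated correlation). Ms4a1 fell from 11.2 ± 8.37 to 2.59 ± 0.434 CPM (-2.11, adjusted p = 0.0434). Ms4a1 lost this call with any library left out other than 12-month replicate 3. The adjusted p was 0.122 and 0.172 without 12-month replicates 1 and 2, 0.102, 0.124 and 0.0949 without 24-month replicates 1, 2 and 3, and 0.0634, 0.0626 and 0.0691 without 2-month replicates 1, 2 and 3. Cxcr5 was at 4.36 ± 3.15 and 1.06 ± 0.442 CPM (adjusted p = 0.0706), Ltb at 8.59 ± 5.3 and 2.91 ± 1.34 CPM (adjusted p = 0.0774), Jchain at 72.4 ± 45.5 and 99.1 ± 26 CPM (adjusted p = 0.818), and Igha at 73.2 ± 33.8 and 138 ± 163 CPM (adjusted p = 0.698).

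The lists of plasma cell markers (adjusted p = 0.552), immunoglobulin constant regions (0.764), germinal centre B cells (0.79), follicular helper T cells (0.13), cytotoxic lymphocytes (0.809), lymphoid tissue chemokines and lymphotoxin (0.97), high endothelial venules (0.769) and dendritic cells (0.973) were not called. Cxcl13 was at 4.92 ± 3.56 and 4.95 ± 3.08 CPM (adjusted p = 0.993), Cd4 at 4.84 ± 2.67 and 3.14 ± 1.44 CPM (adjusted p = 0.502), Cd3e at 1.99 ± 1.19 and 1.27 ± 0.572 CPM (adjusted p = 0.556), Cd8a at 1.46 ± 0.795 and 1.48 ± 0.558 CPM (adjusted p = 0.99), Bcl6 at 37.4 ± 12.8 and 24.7 ± 5.86 CPM (adjusted p = 0.209) and Ctss at 59.6 ± 5.95 and 61.1 ± 11.5 CPM (adjusted p = 0.927). None of 19 T cell genes passed the test, 0 adjusted over the list alone, and the list was called lower (median -0.78, adjusted p = 0.0106; adjusted p = 0.789 with an estimated correlation). That list call was lost without 12-month replicate 1 (0.138) or 2 (0.238), 24-month replicate 1 (0.164) or the 3 salivary libraries (0.395), and with a mean of at least 1 CPM (0.0985). Of 11 MHC class II genes 1 fell, 3 adjusted over the list alone (median -0.21, adjusted p = 0.0358; adjusted p = 0.793 with an estimated correlation). The list call ended without 12-month replicate 1 (0.111) or 2 (0.516) or 24-month replicate 1 (0.245) or 2 (0.221), and turned in direction without the 3 salivary libraries (0.995). It also ended with a mean of at least 1 CPM (0.0682) and with the replicate block (0.067), and with library totals alone 0 of these genes fell.

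Cd163, a scavenger receptor of tissue macrophages, rose from 0.0877 ± 0.00512 to 0.906 ± 0.151 CPM (log2 fold change 3.33, SE 0.51, adjusted p = 0.00353). Mertk, a receptor for the uptake of dying cells, rose from 2.7 ± 0.459 to 7.04 ± 1.35 CPM (1.38, SE 0.24, adjusted p = 0.00801). Loxl1, an enzyme that crosslinks elastin, rose from 1.05 ± 0.0669 to 3.23 ± 0.855 CPM (1.62, SE 0.27, adjusted p = 0.00571). Acta2 rose from 49.7 ± 2.65 to 78.7 ± 6.82 CPM (0.66, SE 0.11, adjusted p = 0.00454). Oas1a rose from 1.34 ± 0.4 to 3.92 ± 1.13 CPM (1.55, adjusted p = 0.0237). Oas1a lost this call without 12-month replicate 1 (0.0941) or 3 (0.0644) or 24-month replicate 1 (0.0557) or 3 (0.0927). Of 18 macrophage and monocyte genes 3 rose, 8 adjusted over the list alone (median 0.55, adjusted p = 3.62e-07). Of 17 fibroblast and extracellular matrix genes 7 rose, 15 adjusted over the list alone (median 0.77, adjusted p = 1.89e-11). Of 22 genes induced by type I interferon 7 rose, 16 adjusted over the list alone (median 1.17, adjusted p = 9.01e-12). Of 10 complement genes 2 rose, 6 adjusted over the list alone (median 0.79, adjusted p = 2.61e-05). Of 10 cathepsins 2 rose, 3 adjusted over the list alone (median 0.14, adjusted p = 0.00598). Each of these 5 lists had an adjusted p = 0.393 with an estimated correlation. Of 6 granulocyte and mast cell genes 2 rose, 5 adjusted over the list alone (median 2.25, adjusted p = 5.2e-06). Of 10 myoepithelial and smooth muscle genes 4 rose, 5 adjusted over the list alone (median 0.66, adjusted p = 0.000279). Both lists had an adjusted p = 0.354 with an estimated correlation. For 24 against 2 months the myoepithelial and smooth muscle list was not called (median 0.01, camera adjusted p = 0.763). With library totals alone 1 cathepsin and 3 myoepithelial and smooth muscle genes rose. Of 18 cell division genes 0 passed the test, 0 adjusted over the list alone, with the list called higher (median 0.69, adjusted p = 0.00166; adjusted p = 0.688 with an estimated correlation). The cell division list was not called for 24 against 2 months (median -0.43, camera adjusted p = 0.125). None of the 17 genes induced by interferon gamma passed the test, 0 adjusted over the list alone, with the list called higher (median 0.53, adjusted p = 0.00596; adjusted p = 0.736 with an estimated correlation). The list call was lost without 12-month replicate 3 (0.105) or 24-month replicate 3 (0.322). The type I interferon list was not called for 12 against 2 months (median -0.34, which was 0.00 with library totals alone, adjusted p = 0.239).

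Of 12 endothelial genes 1 rose, 1 adjusted over the list alone (median 0.41, adjusted p = 0.0122; adjusted p = 0.475 with an estimated correlation). This list call was lost without 12-month replicate 1 (0.058) or 24-month replicate 3 (0.101). Of 5 erythrocyte genes 0 passed the test, 4 adjusted over the list alone (median 0.88, adjusted p = 0.00503; adjusted p = 0.504 with an estimated correlation). This list call was lost without 24-month replicate 1 (0.126). Of 4 skeletal muscle genes 2 fell, 4 adjusted over the list alone (median -2.87, adjusted p = 0.000402; adjusted p = 0.393 with an estimated correlation), and this call was lost without the 2 libraries of 12 months that hold Acta1 (0.673). Of 15 circadian clock genes 3 fell and 1 rose, 5 and 2 adjusted over the list alone (median -0.35, adjusted p = 0.0122; adjusted p = 0.393 with an estimated correlation). This list call was lost without 12-month replicate 1 (0.0748) or 24-month replicate 1 (0.126). Scaled by library totals alone, 2 clock genes fell and 0 rose, and of the endothelial genes 0 rose. The clock repressor gene Cry2 fell from 14.1 ± 0.149 to 8.77 ± 1.12 CPM (log2 fold change -0.68, SE 0.12, adjusted p = 0.00748). Bhlhe41 fell from 9.28 ± 0.788 to 4.84 ± 0.307 CPM (-0.94, SE 0.15, adjusted p = 0.00513), and the hour of tissue collection is not given in the sources used here. The lists of adipocytes (0.43), MHC class I (0.219), senescence (0.182), the unfolded protein response (0.42) and oxidative phosphorylation (0.79) were not called. Cdkn2a had 1 count over the 12-month group and 96 over the 24-month group, a ratio of 100 with a 95% counting interval of 17.6 to 4000.

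Dio1 rose from 0.0868 ± 0.0579 to 122 ± 23.4 CPM (log2 fold change 10.39, SE 0.26, adjusted p = 3.87e-10). Scgb2b7 rose from 143 ± 80.3 to 6190 ± 3700 CPM (5.44, SE 0.59, adjusted p = 0.000383). Scgb1b7 rose from 31 ± 14.3 to 1020 ± 627 CPM (5.05, SE 0.53, adjusted p = 0.000325). Slc28a1, a nucleoside transporter, rose from 0.157 ± 0.197 to 13.6 ± 6.19 CPM (6.43, SE 0.68, adjusted p = 0.000332). Slco1a6 fell from 9.21 ± 1.19 to 1.23 ± 0.337 CPM (-2.91, SE 0.20, adjusted p = 4.17e-05). Slco1a5 fell from 18.4 ± 5.99 to 2.33 ± 0.605 CPM (-2.98, SE 0.27, adjusted p = 0.000121). Esp23, an exocrine gland-secreted peptide, fell from 23.4 ± 15.3 to 0.143 ± 0.117 CPM (-7.38, SE 0.95, adjusted p = 0.0012; 0.233 with limma voom and sample weights). Scgb2a2 was at 30.9 ± 11.5 and 27.2 ± 11.5 CPM. Ltf (adjusted p = 0.966), Aqp5 (0.894) and Pigr (0.723) did not pass the test.

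The count of 656 genes for 24 against 12 months fell to 312 without 12-month replicate 1, 360 without 12-month replicate 2, 436 without 24-month replicate 2, 386 without 24-month replicate 3, 170 without the 3 libraries with the most salivary gland transcripts and 132 without the 2 with skeletal muscle transcripts. Of those 132 genes 61 rose and 71 fell, so the majority of rises turned into a majority of falls, and 8 lists were called higher and 8 lower, against 11 and 5. Of the 60 calls of single genes that the naming rule covers here, 42 were lost without those 2 muscle libraries, among them Cd163, Mertk, Loxl1, Acta2, Cry2 and Bhlhe41 (adjusted p between 0.10 for Mertk and 0.197 for Bhlhe41), and 36 without the 3 salivary libraries, among them Ighd, Cr2 and Fcer2a (adjusted p between 0.106 for Fcer2a and 0.208 for Ighd). Without the muscle libraries the list calls of cathepsins, cell division, the circadian clock, endothelium, erythrocytes and interferon gamma were also lost (adjusted p between 0.0557 for erythrocytes and 0.439 for interferon gamma).

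**Figure D4:**
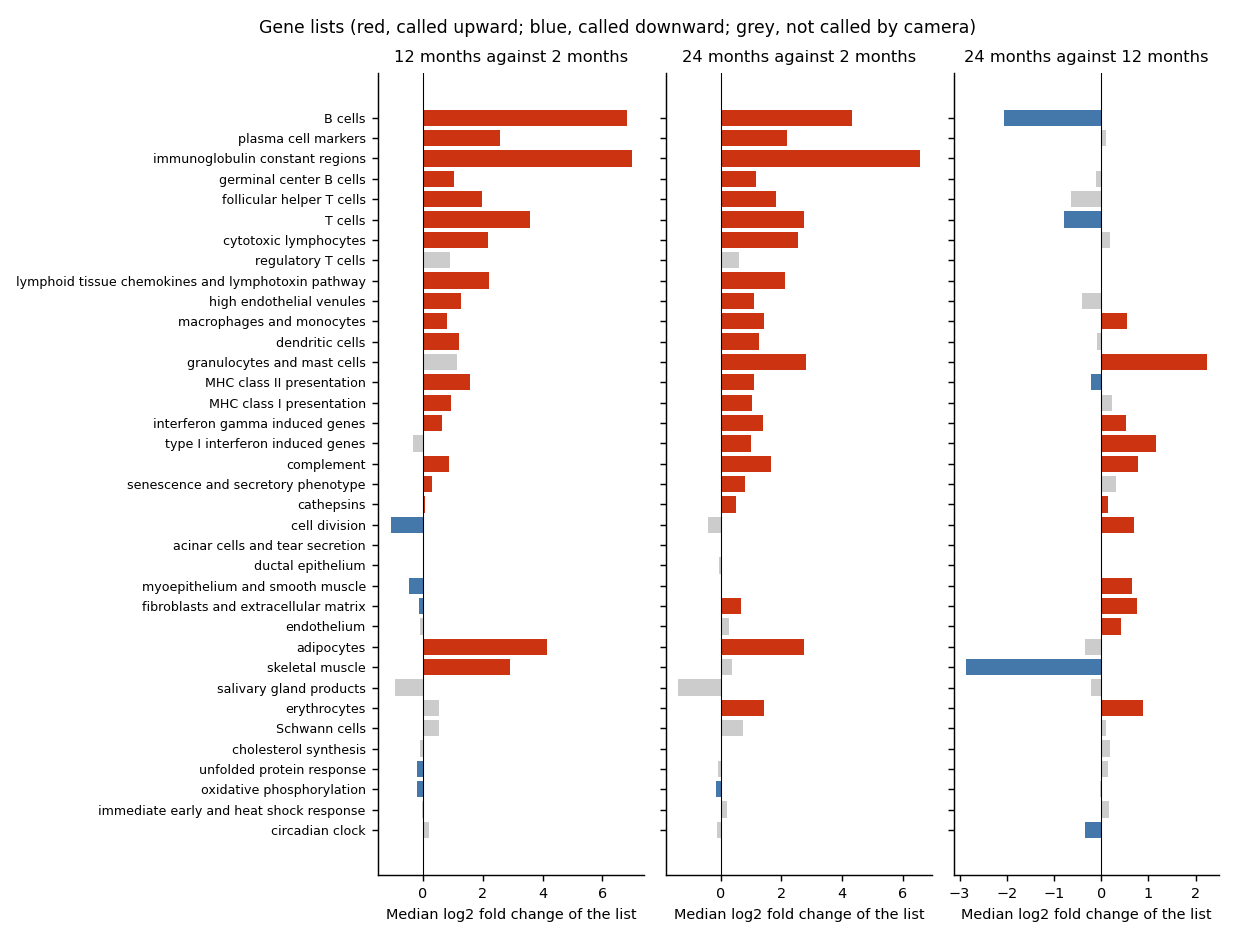
Median log2 fold change of each of the 36 gene lists in the 3 comparisons, with genes of 0 counts at their bound, as bars from 0, red for lists called higher, blue for lists called lower and grey for lists not called; the horizontal ranges differ between panels. B cells had medians of 6.83, 4.34 and -2.07 for 12 against 2, 24 against 2 and 24 against 12 months, and with library totals alone the bars of oxidative phosphorylation and the unfolded protein response (12 and 24 against 2 months), fibroblasts, endothelium, cholesterol synthesis, immediate early genes (12 against 2), ductal epithelium (12 and 24 against 2) the circadian clock (24 against 2) and immunoglobulin constant regions (24 against 12, from -0.01 to 0.01) change sign.

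Across the 3 ages in one test, 2534 of 14944 genes differed (edgeR quasi-likelihood F test, adjusted p under 0.05), 1396 without 2-month replicate 2, 1512 without 2-month replicate 3 and 471 without the 3 libraries with the most salivary gland transcripts. The genes described above moved with age in several ways. Ctss rose by 12 months and did not pass the test between 12 and 24, at 17.1, 59.6 and 61.1 CPM (adjusted p = 9.2e-05), as did Ighm at 3.19, 512 and 577 CPM (adjusted p = 9.2e-05), while Scgb2a2 fell by 12 months, at 314, 30.9 and 27.2 CPM (adjusted p = 6.46e-05). Scgb2b7 was lowest at 12 months, at 2960, 143 and 6190 CPM (adjusted p = 0.000459), and Ms4a1 had its highest mean there, at 0.0358, 11.2 and 2.59 CPM (adjusted p = 0.000458). Its counts were 568, 910 and 93 at 12 months against 92, 99 and 153 at 24 months, so 12-month replicate 3 lay within the range of 24 months. Dio1 (adjusted p = 5.29e-11) and Slco1a6 (adjusted p = 1.74e-05) moved between 12 and 24 months, in opposite directions.

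Immunoglobulin transcripts of all 395 genes made up 0.00626 ± 0.00871% of the counts at 2 months (SD, n = 3), 0.222 ± 0.136% at 12 months and 0.247 ± 0.109% at 24 months, a rise of 0.0106 percentage points per month (two-sided exact permutation test over 1680 arrangements, p = 0.0482). At 2 months the libraries had 0.00147, 0.000995 and 0.0163%, the last in the library with the most Bpifa2. Their heavy chain counts were 340, 182 and 2856, so class shares at 2 months rest on few counts in replicates 1 and 2. The exact permutation p was 0.10 for 12 against 2 months and for 24 against 2, the smallest value that 3 libraries against 3 can give, and 0.70 for 24 against 12. The trend passed 0.05 by little, and its exact permutation p was 0.0982 without 2-month replicate 1 or 2, 0.0946 without 2-month replicate 3, 0.0714 without 12-month replicate 3, 0.104 without 24-month replicate 2, 0.0964 without 24-month replicate 3 and 0.133 without the 3 libraries with the most salivary gland transcripts. Without the 10 most abundant genes in the total the slope was 0.0281 points per month (exact permutation p = 0.044), and with age rank in place of months it was 0.12 points per rank (exact permutation p = 0.0429). Of the heavy chain transcripts, Igha made up 72.5 ± 17.7% at 2 months, 9.49 ± 3.14% at 12 months and 11.4 ± 11.4% at 24 months (exact permutation p = 0.019), Ighm 24.9 ± 18.5, 58.6 ± 3.23 and 63.5 ± 23% (exact permutation p = 0.0393), and the Ighg genes 1.29 ± 1.98, 28.7 ± 5.45 and 24.9 ± 11.7% (exact permutation p = 0.053). Adjusted over the 4 classes, each of these trends had an exact permutation p of 0.0707 and none passed 0.05. Without 24-month replicate 2 the adjusted exact permutation p was 0.0214 for Ighm and 0.0358 for Igha, so this library decides whether those trends pass. Ighd made up 1.35 ± 0.905, 3.13 ± 1.28 and 0.186 ± 0.159% (exact permutation p = 0.325). Thinned to 8 Ighv and 32 Igkv counts per library, the effective number of V segments was 4.12 ± 0.165, 5.69 ± 1.18 and 5.4 ± 1.33 for Ighv (exact permutation p = 0.199) and 4.97 ± 1.54, 10.5 ± 1.4 and 11.7 ± 6.45 for Igkv (exact permutation p = 0.0714). Over all counts, not thinned, the most abundant segment took 41.3, 23.6 and 20.4% of Ighv (exact permutation p = 0.0798) and 40.8, 30.7 and 23.1% of Igkv counts (exact permutation p = 0.126). These shares are not corrected for depth, and few counts can raise them. Ighv counts were 11, 8 and 168 at 2 months, against 399 to 3158 in the older libraries. Single libraries decide these results as well. Without 24-month replicate 1 the exact permutation p was 0.0464 for the number of Ighv segments, 0.00357 for Igkv segments and 0.00179 for the most abundant Igkv segment, and without 12-month replicate 3 it was 0.0446 for the most abundant Ighv segment. With no thinning the slope of the number of segments per month moved from 0.0555 to 0.645 for Ighv (exact permutation p = 0.126) and from 0.299 to 0.773 for Igkv (exact permutation p = 0.0696). T cell receptor segments were too few for a measure, with 0 Trav and 2 Trbv counts in the library with the fewest.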

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

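Leaving out libraries with the most salivary gland or skeletal muscle transcripts, salivary transcripts as a covariate and scaling by library totals alone were chosen after the data were seen, and the other alternatives before. The number of genes called depends on the alternative, while most directions held, and causes were not tested unless stated. With RLE scaling, limma voom, no antigen receptor genes, or only the libraries compared, counts stayed within 1.5 times. Of 293 named gene results called, 78 were called in every setting. Without the 3 libraries with the most salivary gland transcripts 150 of the 293 were lost. With those transcripts as a covariate in all 9 libraries 23 were lost, 10 of them for 24 against 12 months. At an adjusted p under 0.01 the counts for 12 against 2, 24 against 2, 24 against 12 months and the 3 ages were 383, 891, 211 and 842, and with a log2 fold change of at least 1 as well as 0.05 they were 765, 1151 and 281, since fewer genes pass a stricter threshold. No count filter gave 2026 (12 against 2) and 1486 (24 against 12), and DESeq2 gave 1779 and 1198. The replicate block gave 701 (12 against 2), 409 (24 against 12) and 1640 (3 ages). Same-numbered libraries had residual correlations between -0.154 and 0.061, and no library correlated best with one of its own number. The highest value, 0.228, was between 12-month replicate 3 and 24-month replicate 1. Without the 3 libraries with the most salivary gland transcripts, which leaves 6, the counts were 127, 626, 170 and 471, against 1038, 2206, 539 and 2104 with those transcripts as a covariate in all 9, and the immunoglobulin share rose by 0.00919 points per month (exact permutation p = 0.133). Without those 3, the MHC class II list for 24 against 12 months turned in direction (adjusted p = 0.9954). Without the 2 libraries with skeletal muscle transcripts, which leaves 1 of 12 months that is assumed to vary like the others, the counts were 746 (12 against 2) and 132 (24 against 12), and Atp2a1, a calcium pump of skeletal muscle, turned to a log2 fold change of -0.34 (adjusted p = 0.807) for 12 against 2 months. Library totals alone gave 340 (24 against 12). With an estimated correlation 0, 0 and 0 lists were called for 12 against 2, 24 against 2 and 24 against 12 months, and the fry test called 17, 23 and 1. With 1 library left out, the counts ran from 435 to 1285 (12 against 2), 1160 to 2623 (24 against 2), 312 to 700 (24 against 12) and 1396 to 2532 (3 ages). The slope of the immunoglobulin share ran from 0.00964 to 0.0141, of the Ighm share from 1.21 to 2.39, of Igha from -3.19 to -2.07, of Ighv diversity from 0.0352 to 0.093 and its top segment from -1.15 to -0.694, of Igkv diversity from 0.179 to 0.46 and its top segment from -1.28 to -0.505.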

Other observations

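The gene families below, Socs2 and Cish, and every test of an explanation except the counts of other splits were chosen after the result was seen. The Fisher exact tests of families take each gene as independent, so their p-values can be far too small where members move together. At 24 against 2 months 40 of 49 tested Rpl genes and 30 of 42 Rps genes were lower (Fisher exact test, adjusted p = 3.68e-33 and 1.14e-21, medians -0.62 and -0.59), and with library totals alone 10 and 7 were lower (medians -0.31 and -0.28). Families were taken by the start of the gene symbol alone. Genes of ribosomal proteins carry the symbols Rpl and Rps, but genes of other functions that share this start can be among those counted. At 24 against 12 months 9 Rpl and 10 Rps genes were lower (Fisher exact test, adjusted p = 1.22e-05 and 1.83e-07). At 24 against 2 months 6 of 13 Esp genes, exocrine gland-secreted peptides, were lower (Fisher exact test, adjusted p = 0.0201), and 9 of 16 Clec genes, C-type lectins of immune cells, were higher (adjusted p = 0.00085 in that exact test). Reads of near-identical Esp genes can be assigned to one another. Socs2 and Cish, feedback inhibitors of cytokine signalling, rose between 12 and 24 months, Socs2 from 6.23 ± 0.225 to 28.8 ± 6.39 CPM (edgeR adjusted p = 8.17e-05) and Cish from 5.33 ± 1.01 to 17 ± 0.64 CPM (edgeR adjusted p = 0.000146). In 24-month replicate 3, Gm1553 had 135946 counts, against 1306996 and 1122279 in replicates 1 and 2, and Esp15 had 14533, against 221220 and 342018.

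The B cell list was called lower at 24 than at 12 months, with 7 of 20 genes down, a list call lost with an estimated correlation (adjusted p = 0.396) and with the fry test (adjusted p = 0.194). Scaling set by a few abundant genes moves every gene alike and was argued against, since the median log2 fold change of the list lay at -2.05 from that of all genes (SD of the list 1.16). Salivary gland tissue as the whole cause was argued against by a median of -1.33 (SD 1.23) without the 3 libraries that hold the most of it, against -2.07 (SD 1.16) with them. Lymph node tissue in the 12-month samples and a change with age cannot be told apart: the T cell list had a median of -0.78, and the 2 counts of Ccl21 over all 9 libraries decide nothing, since reads of its near-identical copies may have been dropped before counting. Ccl19 had 2, 12 and 0 counts at 12 months and 4, 2 and 6 at 24 months, too few to decide. Age stays open and untested as a cause.

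Secretoglobins were lower at 12 than at 2 months, 15 of 24 tested (Fisher exact test, adjusted p = 6.7e-16, median -2.75), and 17 of 24 were higher at 24 than at 12 months (Fisher exact test, adjusted p = 8.92e-19, median 4.2). For the fall of the family's summed share, reads counted under other members were argued against, since gains of other members made up 15.7% of the losses. Abundant members weigh most in this sum. Scgb2b24 had 3.82, 3.68 and 4.6% of the counts at 2 months and 2.42, 1.88 and 2.4% at 12 months. The sum cannot decide for less abundant members such as Scgb2b7, Scgb1b7 and Scgb2a2. Reads of near-identical copies that were dropped before counting may also lower secretoglobins, which was not tested and stays open. The acinar list had a median of 0.04 (SD over genes 0.96), so secretoglobins, with a median of -2.75, fell more than the median acinar gene. This cannot decide on a lower share of secretory cells in general. Where such cells make most of the RNA, scaling can hide a fall in their share. The list lay 0.03 above the median of all genes, both with TMM and with library totals alone (median 0.34). The list holds genes of acinar cells in general, so it cannot decide on a part of these cells. For the rise, losses of other members made up 99.3% of the gains, so a change of expression and a shift of reads between members cannot be told apart. Age stays open and untested for both.

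Other splits of the libraries into groups of the same sizes were counted. The real grouping was the only 1 of 10 splits with as many genes for 12 against 2 months (highest other 0), 1 of 10 for 24 against 2 (highest other 0) and 1 of 10 for 24 against 12 (highest other 2), where the share cannot fall under 0.05. For the 3 ages it was the only 1 of 100 splits drawn from 280 (highest other 786).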
